A study of Mus musculus with 4 samples.

How the data were processed

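UMI counts per gene and cell were taken from the deposited tables, 1 for each genotype. Per the submitters' processing notes, reads were counted with Cell Ranger 2.0.0 against mm10, and Seurat 2.0 and DESeq2 1.14.1 were used downstream. Read length, chemistry version, sequencing depth per run, the filter that turned barcodes into cells and the number of embryos pooled are not given in the sources used here. Per the labels, the samples of a genotype were repeat sequencing runs of the same material, so each genotype counted as 1 library. All barcodes ended in the same suffix, the runs could not be separated, and the raw reads were not analysed here.

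The deposited values were whole numbers for 27998 gene identifiers, of which 27645 were given a symbol from the GENCODE M21 annotation (GRCm38, the same build as mm10). The other 353 held 0.0274% of control UMIs and 0.0315% of knockout UMIs and entered the totals without being named. Of the genes fixed by name, 3 had no match under that symbol (Amy2b, Ahsp and Oga, which is present as Mgea5). Positions of genes were read from the same annotation.

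The comparisons, the filters, the fixed gene lists, the marker lists and most alternatives were chosen before the data were examined. Barcodes were kept with at least 500 genes and at most 10% mitochondrial UMIs. Doublets were marked by Scrublet, run on each genotype alone through scanpy 1.11.5, and removed. Kept cells of both genotypes were normalised to equal totals, log-transformed and clustered together without correction (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1 with leidenalg 0.10.2, fixed seed). Each marker was scaled to its highest level over the clusters, and a cluster took the name of the marker list with the highest mean, provided at least 5 of its markers were detected (50 CPM and 0.25 of the highest level) and its 10 leading genes held no more markers of another type than of its own. Other clusters stayed unnamed. This naming rule was settled after the data had been seen. All names are marker-based and are written as acinar-like, trunk/ductal-like, endocrine-like, leukocyte-like, mesenchyme-like and mesothelium-like.

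Levels were UMI counts summed over the cells of a class and scaled by the summed total to CPM. Intervals were exact Poisson intervals for levels, exact conditional intervals for ratios and exact binomial intervals for shares, all at 95%. With 1 library per genotype nothing was tested and no count of changed genes was made. Ogt and Mgea5 came first. After them stood the 12 genes with the largest ratio in each direction in all cells and the 8 largest in each direction in every class with at least 30 cells in both libraries. They were ranked by log2 ratio with 10 CPM added to both sides, among genes with at least 50 UMIs in at least 10 cells of the higher library and a ratio of at least 2. Predicted genes, Xist and Y-linked genes were not named, and 19 further genes of the pancreas and of stress responses were followed whatever their value. A gene without a UMI in 1 library was given a lower limit on its ratio, with 3 counts put in place of 0. For a share of 0 cells the limit printed was 3 cells of the total, except for the female-looking control cells in the test of cluster 8, where it was the exact binomial bound.

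For each of 21 fixed lists and 17 marker lists, members with at least 20 UMIs over both libraries were counted as at least 1.5-fold higher, at least 1.5-fold lower or between. The median log2 ratio of a list was placed among 10000 random lists of the same size matched on mean level in 20 bins. The percentile describes these libraries and is no p-value. Shares of cells with transcripts of a gene or list were taken after thinning each cell to 5000 UMIs, and cells with fewer were left out (81 control and 1 knockout cell for Ogt).

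The ratio interval and a 2-fold limit on the ratio with 10 CPM added to both sides were tested on simulated data. These were drawn from the mean profile of the libraries at their own depths, with 200 of 10788 genes given a set ratio. The interval held the set ratio for 94% of genes at 0.25, 98% at 0.5, 96% at 2, 94% at 4 and 95.4% of the 10588 unchanged genes. Counts were drawn with counting error only, which the interval assumes, so this checks the calculation alone. Spread between cells and the smaller totals of single classes were not simulated. The 2-fold limit with 10 CPM added was reached by 60% of genes set at 0.25, 6% at 0.5, 6% at 2 and 94% at 4. The rule that named genes used the ratio without added CPM, together with count floors, so these shares do not describe it.

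Alternatives covered the filters, doublet removal, clustering resolution, clustering each genotype alone, TMM scaling (edgeR 4.0.16), median-of-ratios scaling (DESeq2 1.42.0), totals without enzyme, hormone, ribosomal and mitochondrial genes, means of cells' own levels, the pseudocount, count floors, thinning and control class shares. Further alternatives were added after the data had been seen. They were subtraction of free RNA, a 2-fold floor over the level in leukocyte-like cells, control cells with at least 3 Xist UMIs and no Y-linked UMI, joining of clusters 8 and 9, removal of the 5 cells with most Prss1 or Neurog3, a floor of 15 cells per class and epithelial-like cells as denominator. Leaving out the highest cells shows how far a value rests on few cells and is no estimate of the ratio, since it selects on the gene itself. Free RNA was estimated per class and library as the median share of the library profile shown, in epithelial classes, by leukocyte and mesenchyme markers. Analyses ran in Python 3.11.15 with anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-image 0.26.0 and matplotlib 3.10.9, and in R 4.3.3.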

Results

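The control library held 941 barcodes with 11973979 UMIs (median 10756 per barcode, 3158 genes), and the knockout-labelled library held 617 with 11064540 UMIs (median 15367, 4202 genes). Both came from embryonic pancreas at E15.5. After filtering, 919 control cells and 555 knockout cells remained and formed 18 clusters. The labels give 1 library per genotype, sequenced repeatedly. The animals labelled wild type carried unrecombined floxed Ogt per the series design. Control cells were sorted on E-cadherin and knockout cells on lineage GFP, so genotype and sort cannot be told apart anywhere below. All intervals cover counting error only, not the spread between cells or animals, and no difference has a replicate check.

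Ogt, the targeted gene, which encodes the enzyme that adds O-GlcNAc to proteins, stood at nearly the same level over all cells of both libraries. It measured 61.9 CPM (UMIs scaled by the library or class total) in 919 control cells (727 UMIs, 57.5 to 66.6) and 57.0 in 555 knockout-labelled cells (597 UMIs, 52.5 to 61.8), a ratio of 0.921 (0.825 to 1.03). TMM and DESeq2 scaling multiplied this all-cell ratio by 0.778 and 0.781. The libraries also differed in their mix of cell classes, so the all-cell values do not compare like cells. In epithelial-like cells Ogt was lower in the knockout library, 57.1 against 37.3 (ratio 0.654, 0.520 to 0.826, 112 and 235 UMIs). Acinar-like cells gave 37.1 and 38.0 (48 and 113 UMIs), trunk/ductal-like cells 86.7 and 62.9 (43 and 53 UMIs), and endocrine-like cells 122.7 and 29.5 (21 UMIs in each library, ratio 0.241, 0.125 to 0.463). Leukocyte-like cells, outside the pancreatic lineage, held 62.8 in control and 49.1 in knockout.

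Within the knockout library Ogt was highest in mesenchyme-like cells (108, 186 UMIs) and mesothelium-like cells (94.8, 101 UMIs) and lowest in the unnamed cluster 8 (27.1, 20.01 to 35.98). At 5000 UMIs per cell, 40.8% of mesenchyme-like and 15.7% of cluster 8 cells showed an Ogt UMI. In acinar-like cells these shares were 16.7% of 48 control and 19.4% of 93 knockout cells, and in endocrine-like cells 33.3% of 15 and 9.52% of 42. Ogt lies on the X chromosome (101640060 to 101684351, plus strand, mm10). The labels do not give the deleted exons, and a tag at the end of the transcript may lie outside them, in which case its count does not check the deletion. Restricting control acinar-like cells to the 4 with at least 3 Xist UMIs and no Y-linked UMI gave an Ogt ratio of 0.529, and joining cluster 8 to the trunk/ductal-like class gave 0.446.

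**Figure D1:**
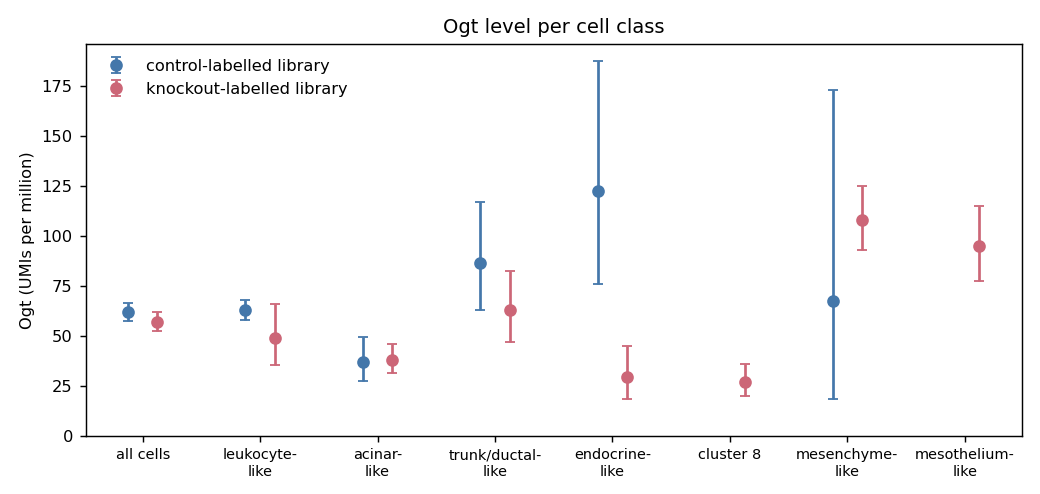
Ogt in CPM (y axis) for all cells and each cell class (x axis) in the control and knockout-labelled libraries; points are summed UMIs and bars exact 95% Poisson intervals. Levels were close in all cells (61.9 and 57.0), where the class mix differed, and in acinar-like cells (37.1 and 38.0). They were apart in endocrine-like cells (122.7 and 29.5).

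Mgea5 (chromosome 19, 45750259 to 45783837, minus strand), whose product removes O-GlcNAc, measured 37.6 in control and 25.4 in knockout over all cells (ratio 0.675, 0.578 to 0.788). In acinar-like cells Mgea5 stood at 17.0 and 16.2, in trunk/ductal-like cells at 36.3 and 30.8, and in endocrine-like cells at 64.3 and 29.5 (11 and 21 UMIs). Gfpt1, which encodes the entry enzyme of the hexosamine pathway, was level in acinar-like cells (41.0 and 41.4) and trunk/ductal-like cells (36.3 and 32.0). Of the O-GlcNAc and hexosamine genes, 12 were measured in acinar-like cells, with 1 higher, 1 lower and 10 between (median log2 ratio -0.01). Xist was found in 99.1% of knockout cells, with no Y-linked UMI, while 22.6% of control cells held Xist and 53.1% Y-linked UMIs, a mix of sexes.

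Leukocyte-like cells made up 801 of 919 control cells (87.2%, 84.8 to 89.3) and 56 of 555 knockout cells (10.1%, 7.71 to 12.9). Mesenchyme-like and mesothelium-like cells together made up 0.762% of control and 37.5% (33.4 to 41.7) of knockout cells. Mesothelium-like cells, marked by Upk3b and Wt1, were absent from the control (0 cells, which allows up to 0.326%, or 3 of 919) and formed 11.9% of the knockout library. Epithelial-like cells were 105 (11.4%, 9.44 to 13.7) and 266 (47.9%, 43.7 to 52.2), although both sorts were aimed at the epithelium. Because the sort differs with genotype, these shares describe the libraries and not the embryos.

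Among epithelial-like cells, acinar-like cells made up 47.6% (37.8 to 57.6) in control and 35.0% (29.2 to 41.0) in knockout. The trunk/ductal-like cluster 9 made up 33.3% (24.4 to 43.2) and 15.8% (11.6 to 20.7), and endocrine-like cells 19.0% (12.04 to 27.9) and 15.8%. Cluster 8 held 33.5% (27.8 to 39.5) of the knockout epithelial-like cells and none of the control (which allows up to 2.86%, or 3 of 105). Clustered alone, the control library gave 57.4% trunk/ductal-like and no endocrine-like cells among its epithelial-like cells. Acinar-like cells themselves lay in separate clusters: cluster 12 held 49 of the 50 control cells, and cluster 6 all 93 knockout cells and 1 control cell. Cluster 13, led by the lymphoid genes Cd7, Ltb and Igll1, made up 0.653% and 4.50% of all cells. There was no separate lymphoid marker list. The cluster stayed unnamed, with 3 markers of its nearest list detected, and was not counted among the leukocyte-like cells above.

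**Figure D2:**
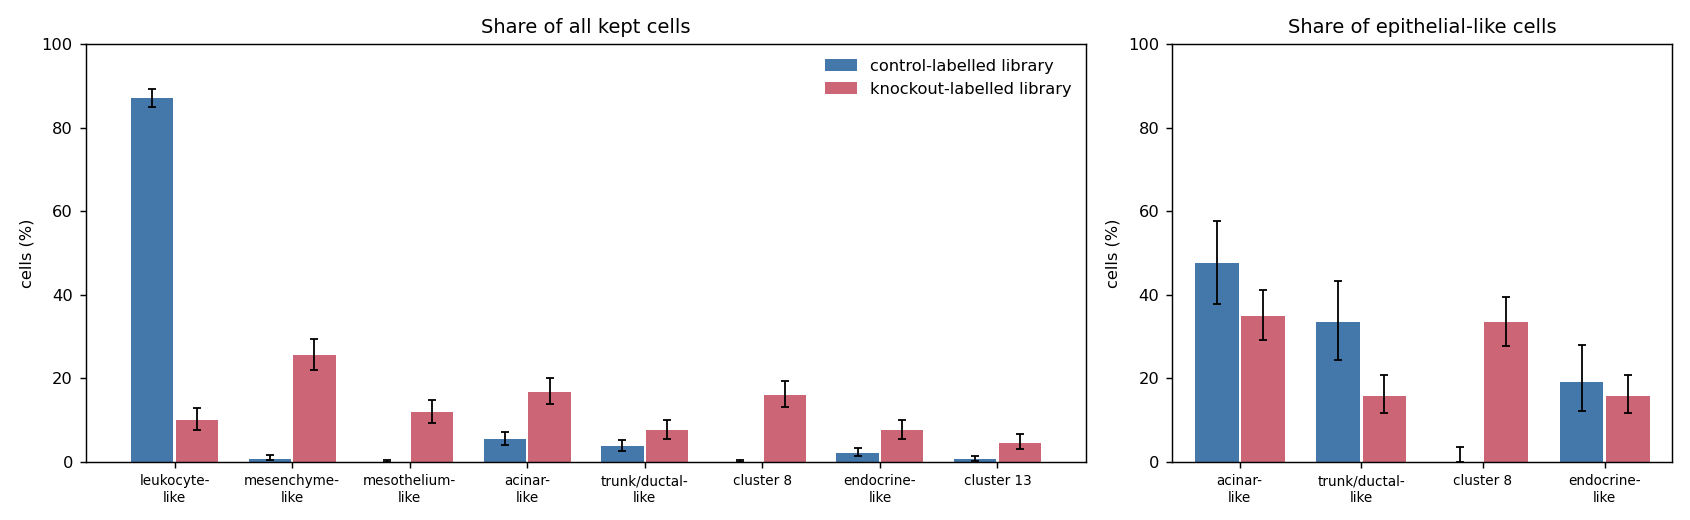
Share of cells in percent (y axis) per cell class (x axis), of all kept cells (left) and of epithelial-like cells (right), in control and knockout-labelled libraries; bars are shares and whiskers exact 95% binomial intervals. Leukocyte-like cells were 87.2% and 10.1% of all cells, and cluster 8 was 33.5% of knockout epithelial-like cells.

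Over all 919 control and 555 knockout cells, complement and chemokine genes were among the largest differences on the control side and collagen genes among those on the knockout side. On the control side stood the complement genes C1qc (1660.4 against 90.8, ratio 0.0547), C1qb (2001 and 125) and C1qa (1445 and 97.6), the chemokine genes Pf4 (1965 and 113) and Ccl24 (162 and 4.30), and Apoe (11814 and 868), which encodes a lipid carrier. The receptor genes Cx3cr1 (466 and 23.3), Mrc1 (418 and 20.4), Stab1 (510 and 27.7), Csf1r (722 and 47.9) and Fcgr3 (744 and 54.3) and the transglutaminase gene F13a1 (824 and 54.5) completed that side. Higher in knockout were the collagen genes Col1a1 (41.6 and 866.5), Col3a1 (47.2 and 960.5) and Col1a2 (27.2 and 538), and the matrix genes Sparc (70.7 and 988) and Dcn (22.1 and 344).

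The other genes of the knockout side were Cym (0.851 and 364, ratio 428, 232 to 892), which encodes the stomach protease chymosin, the antiprotease gene Serpina1b (3.66 and 269), and S100a9 (10.1 and 298), a neutrophil calcium-binding protein gene. With them stood the mast cell protease gene Cma1 (0.0851, 1 UMI, and 112), the membrane protein gene Itm2a (36.8 and 571), the cell cycle inhibitor gene Cdkn1c (101 and 1317) and Igfbp2 (4.17 and 154), which binds insulin-like growth factors. Of these 24 genes, 7 kept a place among the 12 largest ratios of their direction when control class shares were given to both libraries.

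Marker lists over all cells went the same way as the shares. Leukocyte markers were lower in knockout (all 13 members at least 1.5-fold, median log2 -3.01), and mesenchyme (18 of 18, 2.95), mesothelium (8 of 8, 1.43), trunk/ductal (19 of 23, 1.44), pan-endocrine (16 of 16, 1.07), acinar (14 of 25, 0.76) and epithelial sort genes (10 of 10, 1.85) were higher. Neural (9 of 9, 0.46), gut (4 of 4, 0.39), liver (5 of 6, 1.33) and endothelial markers (4 of 6, 0.34) were also mostly higher. Still, 1 liver and 1 endothelial marker were lower, and the summed liver level fell from 633 CPM in control to 488 in knockout. Of 4 erythroid markers 2 were lower and 2 between (-0.53). Of the stomach markers 1 was measured. Immediate early and heat shock genes, which respond to tissue dissociation, were mostly lower (12 of 22, -0.54, against 0.17 for the median gene).

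Acinar-like cells of the knockout library (93 cells, cluster 6) held less RNA of several digestive enzyme genes than those of the control (50 cells, cluster 12). Cela3a, an elastase gene, stood at 102 CPM in control and 3.03 in knockout (132 and 9 UMIs, ratio 0.0297, 0.0133 to 0.0581), with a UMI in 29 of 50 and 6 of 93 cells. Aqp8, a water channel gene, measured 78.1 and 18.2 (ratio 0.233), Rnase1, a secreted ribonuclease gene, 77.3 and 13.8 (0.179), and Pdia2, a protein disulfide isomerase gene of the pancreas, 104 and 31.0 (0.297). Ctrb1, the chymotrypsinogen gene, was at 20670 and 11024 (0.533, 0.525 to 0.542), with a median cell at 12928 and 8398. Other enzyme genes were level or higher in knockout: Cpa1, a carboxypeptidase gene, 5666 and 7118 (1.26, 1.22 to 1.29), the colipase gene Clps (ratio 0.929, 0.908 to 0.95) and the trypsinogen gene Prss2, 328 and 566. Prss2 also stood at 31.7 and 184 in leukocyte-like cells of control and knockout, so part of its level may be free RNA. It may also share reads with other trypsin genes.

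Prss1, a trypsinogen gene (chromosome 6, 41458932 to 41463786), measured 781 in control and 93.6 in knockout (ratio 0.120, 0.105 to 0.137), but 84.3% of its control UMIs came from 5 cells. Without the 5 highest cells of each library its ratio was 0.383 (0.305 to 0.481). Cpb1, a carboxypeptidase gene, measured 239.7 and 55.9 (0.233, 0.192 to 0.282), with a ratio of 0.464 without its own 5 highest cells of each library. The trypsinogen-like gene Prss3 measured 163 and 33.0 (0.566, 0.302 to 1.08, without its own 5 highest cells). These cells were chosen for each gene separately and need not be those highest in Prss1. Try10 (577 and 138), Try5 (558 and 172), Amy2a4 (41.0 and 7.07) and Amy1 (42.5 and 9.43) were lower as well, but these trypsin and amylase genes have near-identical relatives and single-gene counts are uncertain. The Tmem245 difference (127 and 23.6), in a membrane protein gene, also lay in few cells (0.639 without the top 5).

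Genes higher in knockout acinar-like cells included Wfdc2, an epithelial antiprotease gene (62.6 and 262, ratio 4.19, 3.33 to 5.33), and Id1 (96.7 and 301, 3.11, 2.58 to 3.78) and Id3 (109.8 and 267, 2.43), which encode inhibitors of basic helix-loop-helix factors. Mdk, a growth factor gene, stood at 276 and 704 (2.55, 2.28 to 2.86), Vtn, the vitronectin gene, at 132 and 327 (2.47), Hspb1, a small heat shock protein gene, at 41.0 and 135 (3.29), and Igfbp7 at 6.96 and 33.3. Serpina1b measured 18.6 and 174 (9.40, 6.24 to 14.8), Serpina1e 14.7 and 85.5 (5.82) and Afp, the fetal carrier protein gene, 14.7 and 57.2 (3.90); Serpina1 paralogs may share reads. Serpina1b also reached 82.1 in knockout leukocyte-like cells, which should lack it, so part of its level was free RNA. Mdk and Wfdc2 reached 326 and 108 in those cells (38.2 and 9.64 in control leukocyte-like cells), so part of their levels may be free RNA too. The same holds for Hspb1, Igfbp7, Serpina1e and Afp, at 54.8, 14.8, 30.8 and 18.3 in knockout leukocyte-like cells. Krt20, a keratin gene (0.773, 1 UMI, and 35.3, ratio 45.7, 8.03 to 1823), had 72.4% of its knockout UMIs in 5 cells, and Gfod2 (11.6 and 61.9) 87.5%.

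The acinar genes above stood at least 2-fold over the leukocyte-like level of the higher library, a limit added after the values had been seen. By size alone the largest differences in the class were mostly genes of other cells: Pf4, C1qb, C1qc, Fcer1g, Apoe and Stab1 in control, and Cym (0.773 and 149), S100a9, Col3a1, Pyy, Ghrl, Sparc and Col1a2 in knockout. Of the 8 genes on each side, 6 and 7 lay at or below 2-fold of their leukocyte-like level, as free RNA would. Marker genes of other classes stood in acinar-like cells at 17.7% of the library level in control and 23.8% in knockout. In leukocyte-like cells Ctrb1 reached 1368 and 1978 and Cpa1 264 and 896.

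**Figure D3:**
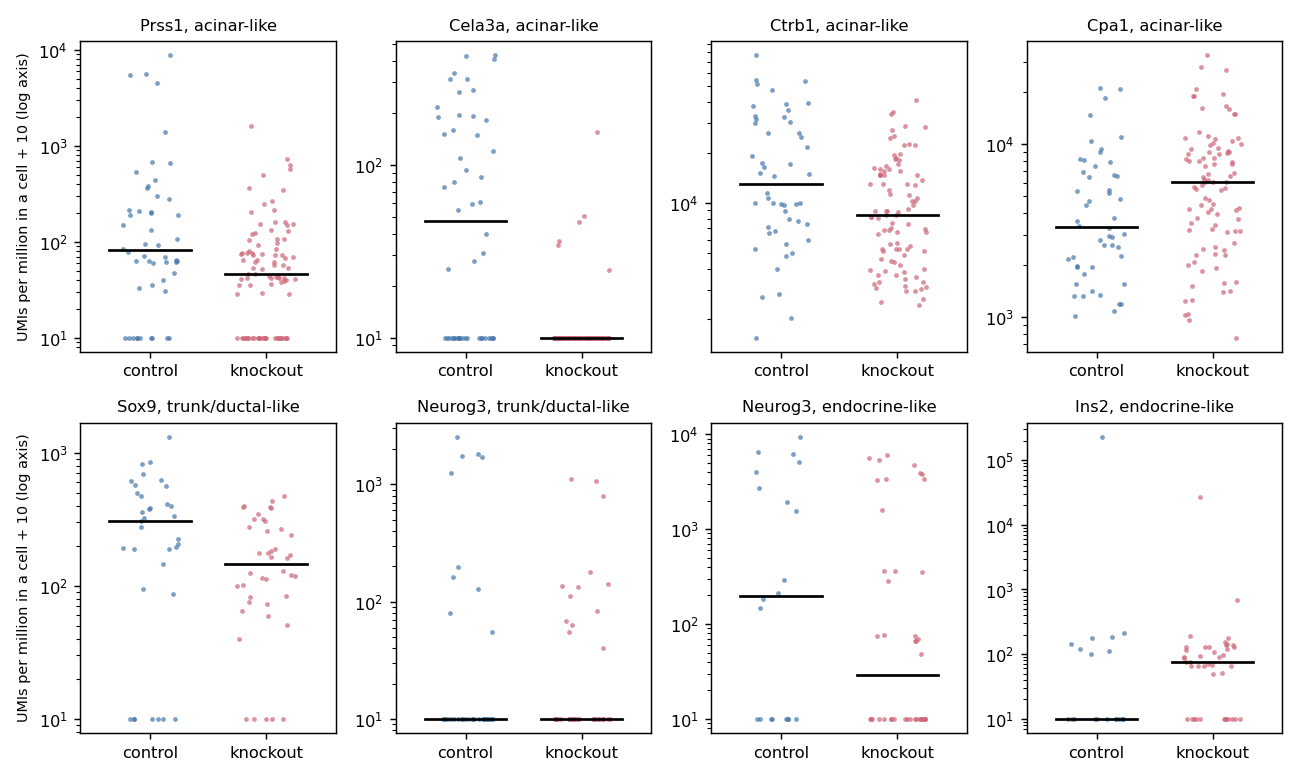
CPM of single cells, with 10 added (y axis, log scale), in control and knockout-labelled libraries (x axis) for genes of acinar-like, trunk/ductal-like and endocrine-like cells; points are cells and black lines medians. Prss1 reached over 1000 in 5 control and 1 knockout acinar-like cell, while Ctrb1 was spread over the class (medians 12928 and 8398).

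In acinar-like cells Ptf1a, the acinar master regulator, measured 296 and 246 (ratio 0.831, 0.733 to 0.943), Pdx1, the pancreas homeobox gene, 59.5 and 42.8 (0.718), and Bhlha15, which drives secretory maturation, 89.7 and 43.4 (0.484). Sox9 stood at 44.8 and 57.2, Nkx6-1 at 17.0 and 17.2, Cdh1 at 142 and 117, and Epcam at 642 and 623. Neurog3 (55.7 and 29.6) sat in few cells, and the hormone genes Ins1 (31.7 and 29.3) and Ins2 (85.8 and 60.6) were near their leukocyte-like levels (39.5 and 102 in control). Gcg measured 16.2 and 15.1, with 90.5% of its control UMIs in 5 cells. Of the pancreatic transcription factors 24 were measured, 3 higher, 3 lower and 18 between (median log2 -0.03).

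Of 24 unfolded protein response genes, which serve protein folding in the secretory pathway, none was higher in knockout acinar-like cells, 9 were lower and 15 between (median log2 -0.46, below all random lists). Among them stood the chaperone gene Hspa5 at 928 and 687 (0.740, 0.689 to 0.795), Sdf2l1 at 436 and 207, Edem1 at 179 and 88.5, and Hsp90b1 at 776 and 504. Of 21 integrated stress response genes 3 were lower and 18 between (-0.14), with Cebpb at 107 and 41.4, Psat1 at 99.7 and 57.6 and Ddit3 at 17.0 and 14.5. The acinar marker list itself had 4 higher, 10 lower and 10 between (-0.35). With the control limited to its 4 female-looking cells, the acinar list median turned to 0.15, the unfolded protein response median was -0.14, and Cpa1 came to a ratio of 2.69 and Prss1 to 0.433.

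Of 21 trunk/ductal markers in acinar-like cells 7 were higher, 1 lower and 13 between (median log2 0.34), and of 11 Hippo targets 4 were higher (0.26). Both lists stood further apart in leukocyte-like cells (1.53 and 0.58). Those cells were of different kinds in the libraries, so this cannot tell free RNA from their own expression. Spp1, the osteopontin gene, was at 142 and 359.9 and at 391 in knockout leukocyte-like cells, and Hes1, a Notch target, stood at 295 and 423. Of 39 mitosis genes 4 were lower and 35 between (-0.22), with the proliferation gene Mki67 at 81.2 and 44.4 and Ube2c at 424 and 265, while replication genes were level (32, 30 between, 0.03). Immediate early and heat shock genes had 7 of 21 lower (-0.10), among them Klf2 at 82.7 and 18.9 and Fos at 576 and 309. Trp53 measured 81.2 and 119 (1.47, 1.18 to 1.84), Cdkn1a, a p53 target and cell cycle inhibitor gene, 87.4 and 113 (1.30), Mdm2 23.2 and 25.2, and 22 p53 targets had 3 higher, 3 lower and 16 between (0.03).

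The remaining lists in acinar-like cells lay near the median gene (log2 0.03). They were apoptosis (22 measured, -0.02), ribosomal proteins (83, 0.09), oxidative phosphorylation (76, 0.08), mitochondrially encoded genes (13, -0.01), glycolysis (14, 0.04), hypoxia (16, -0.07), Notch signalling (13, -0.12), cholesterol synthesis (20, 0.15), mTORC1 and autophagy (17, -0.09), epithelial sort genes (10, 0.16) and splicing genes (15, 0.17). Txnip, which responds to glucose, stood at 78.1 and 84.2. Leukocyte markers (13, -2.39), mesenchyme markers (16, 1.32), mesothelium markers (3, 1.08) and hormone genes of delta, epsilon and PP cells (6, 0.97) went in the direction of the free RNA of each library, while liver markers (5, 1.45) held Afp and Serpina1b. Endocrine progenitor (14, -0.06), Fev stage (8, 0.10), beta (9, -0.09), alpha (9, 0.18), pan-endocrine (10, -0.09) and neural markers (3, 0.25) lay between, and 4 sex-linked genes had a median of -0.34.

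In trunk/ductal-like cells of cluster 9 (35 control and 42 knockout cells), the duct and progenitor regulators Sox9 and Nkx6-1 were lower in knockout. Sox9 measured 304 and 154 CPM (ratio 0.506, 0.398 to 0.645), with a median cell at 296 and 135, and Nkx6-1 143 and 85.4 (0.597, 0.424 to 0.840). Pdx1 (48.4 and 52.2), Cdh1 (165 and 139) and Epcam (738 and 795) were close. Neurog3 (chromosome 10, 62133090 to 62134763), which starts endocrine commitment, measured 224 and 80.6 (0.3604, 0.263 to 0.492), with 94.6% of control UMIs in 5 cells. Without the 5 highest cells of each library its ratio turned to 1.19 (0.413 to 3.86), with cluster 8 joined to the class it was 0.161, and 10 control and 13 knockout cells held a Neurog3 UMI.

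Cyclin genes of cluster 9 went in opposite directions: Ccnd1 at 151 and 306 (2.02, 1.56 to 2.65) and Ccnd2 at 209.6 and 86.6 (0.413, and 0.240 after subtraction of free RNA). The growth regulator gene Dlk1 stood at 321 and 899 (2.80, 2.36 to 3.35), but at 442 in knockout leukocyte-like cells, and its ratio after subtraction of free RNA was 1.65. Also higher in knockout were the matrix gene Fbln1 (22.2 and 75.9), the stress factor gene Maff (32.3 and 86.6), and the cysteine and glutathione enzyme genes Cdo1 (46.4 and 103) and Gsta4 (40.3 and 83.0). Col27a1, a collagen gene (119 and 51.0), and Nav2, a cytoskeletal regulator gene (133 and 65.2), were lower. These genes passed the later 2-fold limit over leukocyte-like cells; by size alone all 8 genes on each side were background, with Pf4, Stab1 and C1qb in control and Col1a2, Col3a1, Itm2a, Ghrl and Prss2 in knockout.

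The replication and mitosis lists had medians on the higher side in knockout cluster 9 cells, with 14 of 29 and 18 of 36 members between. Of 29 replication genes 15 were higher and none lower (median log2 0.56), with the endonuclease gene Fen1 at 16.1 and 54.6, Rrm2 at 48.4 and 127 and Mcm7 at 58.5 and 122. Of 36 mitosis genes 18 were higher and none lower (0.52), with Tpx2 at 22.2 and 72.3, the topoisomerase gene Top2a at 42.3 and 110.3 and Nusap1 at 36.3 and 80.6. Cdkn1a measured 143 and 192 (1.34, 1.01 to 1.80), Trp53 129 and 152 and Mdm2 44.3 and 45.1. Against female-looking control cells alone the replication median was 0.65, the mitosis median 0.13 and the Sox9 ratio 0.762.

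In cluster 9 trunk/ductal markers had 1 higher, 5 lower and 16 between (median log2 -0.21, and -0.0443 against female-looking control cells), with Anxa3 at 50.4 and 8.30, Glis3 at 30.2 and 8.30 and Bicc1 at 383 and 255. Pancreatic transcription factors (14, 5 lower, -0.32), Hippo targets (10, 5 lower, -0.40) and immediate early genes (20, 5 lower, -0.20) had medians on the lower side. The p53 targets (17, 3 higher, 0.16), the unfolded protein response (20, 18 between, 0.07), the integrated stress response (21, 3 higher, 0.12) and O-GlcNAc genes (11, 9 between, -0.18) were level, with Hspa5 at 562 and 591, Ddit3 at 20.2 and 14.2 and Txnip at 181 and 155. Acinar (18, 12 higher, 0.66), mesenchyme (13, 11 higher, 1.90) and leukocyte markers (12, all lower, -2.63) went in the direction of the free RNA. Cpa1 (304 and 855), Ptf1a (14.1 and 24.9), Ins1 (38.3 and 33.2) and Ins2 (92.7 and 61.7) were also read as free RNA. Subtraction did not level the acinar genes, with ratios of 8.14 for Try5, 4.41 for Cpb1, 1.83 for Try10 and 0.865 for Prss3. How far free RNA accounts for them is thus not settled.

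Cluster 8 (89 knockout cells, none from control) combined duct and keratin genes with secreted protease and antiprotease genes. Cym (chromosome 3, 107211293 to 107221732) led it at 1473 CPM (1417 to 1530), followed by Serpina1b at 789.8, Serpina1a at 311 and Spp2, a secreted phosphoprotein gene, at 136; as leading genes they define the cluster. Its cells also held Krt18 (2536), Krt8 (1824), Krt7 (458), Spp1 (2095), Clu (1459), Bicc1 (341), Sox9 (171) and Epcam (597), and 18 trunk/ductal markers were detected. The metal-binding genes Mt1 and Mt2 stood at 5485 and 4220.1, with Mt1 at 1816 in cluster 9 and 2457 in acinar-like cells of that library. Pdx1 (32.2), Nkx6-1 (44.7) and Neurog3 (14.7) were low. A cluster from 1 library may be a property of that library and not a cell type.

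Endocrine-like cells (20 control and 42 knockout cells, a class below the size fixed in advance) differed in their mix of hormone genes, which sat in single cells. Ins2 measured 10863 and 1246 and Ins1 4003 and 1327, with 1 cell over 1000 CPM in each library for either gene, so the insulin values described single cells. The glucagon gene Gcg stood at 818 and 1767 (2 and 5 cells over 1000), the amylin gene Iapp at 730.4 and 3771 (2 and 10 cells), and Ppy, the pancreatic polypeptide gene, at 117 and 723 (1 and 3 cells). Neurog3 was at 2489 and 997 (0.400, 0.355 to 0.453), with 8 of 20 and 10 of 42 cells over 1000.

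Serpina1c measured 245 and 1435 in endocrine-like cells, with 1 and 17 cells over 1000, and Serpina1b 0 and 624 (at least 35.6-fold, with 8 knockout cells over 1000 CPM), although these paralogs may share reads. Malat1, a nuclear RNA, stood at 30083 and 14829, with a median cell at 30396 and 14654, and Runx1t1, a precursor stage factor gene, at 321 and 145. Hspa5 (421 and 717, 1.70, 1.33 to 2.21), Cdkn1a (596 and 769), Pdx1 (76.0 and 97.0) and Nkx6-1 (175 and 209) were higher or close. Endocrine progenitor markers had a median on the lower side (16 measured, 8 lower, 2 higher, 6 between, median log2 -0.51), as had Fev stage markers (11, 4 lower, 7 between, -0.35). Alpha markers (14, 7 higher, 3 lower, 4 between, 0.56) and delta, epsilon and PP markers (8, 5 higher, 2 lower, 1 between, 1.27) had medians on the higher side. Beta (12, 0.10) and pan-endocrine markers (16, 0.16) were near level, and splicing genes had 6 of 14 lower (-0.26). Markers of other cells also differed in this class, with acinar (12 of 15 higher, 0.97) and mesenchyme markers (10 of 12 higher, 2.02) above and leukocyte markers (10 of 10 lower, -2.62) below, and so did replication genes (9 of 14 higher, 0.68) and mitosis genes (10 of 17 higher, 0.61). Its cells held a median of 7576 UMIs in control and 16608 in knockout.

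Leukocyte-like cells (801 control and 56 knockout) were of different kinds in the libraries. Cluster 3, led by the neutrophil genes S100a9 and Ngp, held 12.98% of control and 42.9% of knockout leukocytes, and cluster 16, led by the mast cell genes Cpa3 and Cma1, 0.2497% and 23.2%. The Lyve1 macrophage cluster 1 held 19.6% of control leukocytes and none of the knockout. Over the class S100a9 stood at 11.8 and 2625, Cma1 at 0.104 and 1079 and Ngp at 0 and 503 (at least 1618-fold), so the control cells of cluster 3 nearly lacked its leading neutrophil genes. On the control side Lyve1 stood at 324 and 5.70 and Pf4 at 2275 and 157.

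Almost every acinar-like and cluster 9 cell held replication and mitosis transcripts at 5000 UMIs. Replication transcripts (at least 3 UMIs) were found in 97.9% of 48 control and 97.8% of 93 knockout acinar-like cells, and in 91.4% of 35 (76.9 to 98.2) and 97.6% of 42 (87.4 to 99.9) cluster 9 cells. Mitosis transcripts were found in 100% of acinar-like and cluster 9 cells, so that share did not separate the libraries. The summed mitosis level was 5836 and 4843 CPM in acinar-like cells and 4118 and 5943 in cluster 9. The summed replication level was 2138 and 2299 in acinar-like cells and 1574 and 2443 in cluster 9. Among endocrine-like cells, 66.7% of 15 and 73.8% of 42 held replication transcripts, and among cluster 8 cells 97.8%.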

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

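Of the 9 tests given below, 4 were written down before their results were known and 5 were chosen only after the patterns had been seen: those of epithelial genes, Alb and sex for cluster 8, and those of the spread of ratios and the summed trypsins for acinar enzymes. Subtraction of free RNA and leaving out 5 cells were also chosen after the results had been seen.

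Cluster 8 held 89 knockout cells and no control cell. Epithelial sort genes stood 5.92-fold over leukocyte-like cells (4.35 to 9.03 over 10 genes), against droplets of free RNA. Krt8, Krt18 and Cldn3 of these genes also served to class the cluster as epithelial-like, so this check is not independent of that naming. Alb stood at 2.26 CPM, against liver, though Serpina1b, Serpina1a and Afp of the same marker list stood at 789.8, 311 and 126. Of 20 stomach and gut markers 0 reached 50, which the prediction counted against those organs. Cym, a stomach protease gene outside that list, led the cluster at 1473. No stomach or gut cells of this stage were available to show that they would reach that limit, so those organs stay open. Of 12 female-looking control epithelial-like cells none lay in the cluster, which left room for up to 26.5%, against a lower bound of 27.8% in knockout. This cannot decide on sex. Clustering was uncorrected and acinar-like cells separated by library, so a control cell of either sex may be kept out by library alone. Sex stays open, and genotype, the different sorts, litter and stage stay open and untested.

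Several secretory enzyme genes were lower in knockout acinar-like cells. Reads shared among trypsin paralogs would leave the summed trypsins level. Their ratio was 0.3798 (0.3624 to 0.398, 11 genes), but 0.738 (0.694 to 0.786) without the 5 cells of most Prss1, so sharing stays open for the trypsins. Sharing among trypsins does not bear on Cela3a (0.0297), Rnase1 (0.179) and Ctrb1 (0.533). Whether these shared reads with relatives of their own was not tested. Thinning by free RNA as the whole source would lower all by 1 factor, yet the Cpa1 ratio was 10.5 times the Prss1 ratio (at least 8.93; ratios of 1.47 and 0.383 without the 5 cells of most Prss1), and subtraction of free RNA left Prss1 at 0.117 and Ctrb1 at 0.536. For sex, the 12 control-high genes above the leukocyte-like limit were summed, a set picked from this same comparison and without Ctrb1. On that sum the 4 female-looking control cells stood at 0.819 of the 23 male-looking ones (0.7003 to 1.04 with any 1 cell left out). Knockout cells stood at 0.311 of the female-looking control cells. This leaves a part played by sex open. Genotype, sort, litter and stage also stay open and untested.

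In the knockout library 9.08% of barcodes (56; 6.93 to 11.6) had over 10% mitochondrial UMIs, against 1.70% (16; 0.975 to 2.75) in control, and these were left out of the comparisons. At control class shares the knockout value would be 2.21% (1.64 to 2.77), inside the control interval, and class mix is thus a likely source. Most control barcodes were leukocyte-like (717 of 941), with few over the limit in either library, so this value had little room to show more. Among epithelial-like barcodes the shares were 12.1% of 124 control (6.93 to 19.2) and 16.7% of 323 knockout (12.8 to 21.2), so a difference within that class stays open. Knockout barcodes over the limit had a median UMI count 0.423 of that of the other knockout barcodes, so that damaged cells may also be part of the difference. Whether genotype or handling adds to this was not tested.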

How the results depend on the processing

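Some alternatives were chosen only after results had been seen; these were subtraction of free RNA, the limit over leukocyte-like cells, the sex restriction, joining clusters 8 and 9, leaving out the 5 highest cells, a floor of 15 cells per class and epithelial-like cells as denominator. Leaving out each sequencing run in turn was not possible, since all barcodes end alike and the runs cannot be separated. No paired analysis was possible because each genotype had 1 library. Of 300 alternative values 239 stayed close, 59 moved and 2 were counted as reversed in direction. Close meant inside the interval of the main value or, for sets of named genes, most of them kept. A reversal was counted only where the interval of the main value excluded no change, and never for shares. Ogt ratios over all cells and in acinar-like cells thus changed side in some alternatives without being counted as reversed. The cause of a change was not tested unless stated.

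Over all cells the Ogt ratio was 0.720 with DESeq2 and 0.717 with TMM scaling, and 1.04 as mean of cells' levels. Of 24 named genes 7 kept their place at control class shares and 10 with a pseudocount of 1. Joining clusters 8 and 9 gave an Ogt ratio of 0.446 and a mitosis median of 0.29.

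With female-looking control cells only, the acinar Ogt ratio was 0.529 and the acinar list median in acinar-like cells reversed to 0.15. There the mitosis median was -0.39 and the unfolded protein response -0.14; in cluster 9 the mitosis median was 0.13 and the trunk/ductal median -0.0443. Of 16 named genes 5 (acinar-like) and 3 (cluster 9) remained.

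Leaving out the 5 highest cells moved the acinar median to -0.21 and reversed the Neurog3 ratio in cluster 9 to 1.19, where those cells held most of the Neurog3 UMIs. After subtraction of free RNA the unfolded protein response median was -0.51 in acinar-like cells, and in cluster 9 mitosis was 0.63 and pancreatic transcription factors -0.57 (-0.81 with a floor of 100 UMIs); 8 and 3 named genes remained. The 2-fold limit over leukocyte-like cells left 3 and 0, a pseudocount of 1 left 4 in acinar-like cells, and a floor of 200 UMIs left 3 in cluster 9. Means of cells' levels gave an acinar mitosis median of -0.12.

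Leukocyte-like shares were 14.2% in knockout at resolution 0.5, 14.4% clustered alone and 13.1% with every barcode kept, and 76.8% in control with Scrublet-marked cells kept and 76.2% with every barcode. With every barcode kept, 92 control barcodes lay in clusters named neither leukocyte-like, epithelial-like, mesenchyme-like nor mesothelium-like. These shares thus depend on which clusters receive a name. Clustered alone, control epithelial-like cells were 57.4% trunk/ductal-like and 0% endocrine-like; the strict filter gave 10.5% endocrine-like. Replication transcripts were found in 75.7% of control cluster 9 cells under the strict filter and in 100% in cluster 9 without thinning, in 100% of knockout cluster 9 cells at 2 UMIs, and in 100% of acinar-like cells at 2 UMIs or, in knockout, without thinning.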

Other observations

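Tests and limits used in this part were chosen only after the results had been seen. The gene for corticosteroid-binding globulin, Serpina6, was among the leading genes of cluster 6 and stood at 896 CPM in control and 2072 in knockout acinar-like cells, with 64.5 and 321 in cluster 9 and 43.1 and 301 in leukocyte-like cells. In cluster 8 Serpina6 reached 816. Clu, which encodes a secreted chaperone, was at 986 and 1379 in cluster 9 and at 529 and 639.6 in acinar-like cells.

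In knockout endocrine-like cells Serpina1b and Serpina1a reached 624 and 243, close to their levels of 789.8 and 311 in cluster 8, with 82.1 and 30.8 in leukocyte-like cells of the library. Krt7 was at 596 and 621 in endocrine-like cells, above 242 and 227 in cluster 9.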
